A study of Mus musculus with 46 samples.

How the data were processed

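The series holds 46 samples from mouse: RNA sequencing (RNA-seq), AGO2 enhanced crosslinking and immunoprecipitation (eCLIP) and AGO2 chromatin immunoprecipitation (ChIP). The values used here are 10 RNA-seq libraries in 4 groups and 2 eCLIP peak lists from whole testis cytoplasm. The RNA groups are pachytene control with 2 libraries, pachytene Ago2 conditional knockout (cKO) with 2, round spermatid control with 3 and round spermatid cKO with 3. Per the labels, RNA was extracted with TRIzol and the RNeasy kit, and libraries were made with the KAPA mRNA HyperPrep kit and sequenced from both ends. The labels name neither the strain, nor the Cre driver, nor the deleted exons, and do not say whether replicates are separate animals, so every p measures only the spread between samples.

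Expression was deposited as TPM, the share of each transcript among all transcripts of a library scaled to a fixed total, estimated by the authors with kallisto 0.45.0 per the submitters' processing notes. These notes also name FastQC and DESeq2 without giving their role. Every deposited column adds up to the same total, so TPM keep no read totals and the depth of the libraries is unknown. The eCLIP peaks were deposited by the authors as 1 list per replicate, with a log2 fold enrichment for each peak, taken here as immunoprecipitate over its paired input because the labels pair each with an input. Each list also gives a p-value and a Benjamini-Hochberg adjusted p-value computed by the authors. Upstream of the peaks, cutadapt 1.18 and STAR 2.6.1d with the mm10 genome are named per the submitters' processing notes, and the peak caller is not stated. Every listed peak has a log2 enrichment above 3.3, and the files hold no strand and no read counts, so the depth behind a peak is unknown. The lists therefore show only peaks the authors kept.

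Transcripts were matched by identifier to the GENCODE M21 annotation: 116428 of 117497 matched, and the other 1069 held 0.358% to 0.552% of TPM. TPM were summed to 35907 genes, and the 17622 genes with a mean of at least 1 TPM over the 10 libraries were tested on log2(TPM + 1). A linear model with 1 coefficient for each of the 4 groups was fitted to all 10 libraries with limma 3.58.1 and its mean-variance trend in R 4.3.3. The contrasts were cKO against control in each stage, the difference between these effects, and round spermatid against pachytene in control cells. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Adding 1 before the logarithm makes fold changes of low genes smaller than the ratio of their TPM. With 2 libraries against 2, or 3 against 3, a permutation of labels could not reach p under 0.05, so the tests rest on the spread that limma shares across genes and groups.

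In total 19 gene lists of pathways and cell types were fixed, and X-linked and Y-linked genes were added from the annotation. The 20 lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, and adjusted over the 40 tests of both genotype contrasts together. The calls were repeated with a correlation estimated from the data and with fry, which tests whether a list's genes move on balance in 1 direction and compares them with no other genes. Red blood cell genes had 4 tested members and were not tested. Counts of list members are given over all genes tested and, for most lists, adjusted over the list alone.

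Genes named in the text followed a rule. For each genotype contrast these were Ago1 to Ago4, Dicer1 and Tnrc6a, and up to 12 higher and 12 lower called genes with the largest fold change. Each of the latter needed a mean of at least 5 TPM in the higher group, no overlap between cKO and control libraries, and a symbol not of the Gm-number or Rik kind. The stage contrast took 6 in each direction, each list up to 4 members with the smallest p, the difference of effects 8 genes, and eCLIP the 10 genes with the strongest peak shared by both lists. Genes outside this rule are marked in the text. The contrasts, tests, gene lists, naming rule and most alternatives were set before the data were examined.

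Peaks were assigned by their midpoint to coding sequence (CDS), 3' UTR, 5' UTR, non-coding exon, intron or no gene, in that order, with Wilson 95% intervals that cover counting error only. Overlap between the lists needed 1 nt and was compared with 100 random placements of the other list's peaks within the same genes. Peaks in no gene were placed anywhere on their chromosome, which lowers the random overlap. Because the lists hold no strand, regions, target genes and overlap were assigned without it, and a peak on the opposite strand of a gene is counted in that gene. Windows of 3' UTR peaks extended by 20 nt were searched for 12 microRNA seed matches of 7 nt, against 5 windows of the same width per peak elsewhere in the same 3' UTRs, with Fisher's exact test, two-sided. Target genes had a CDS or 3' UTR peak in both lists. Their median change was also compared with 10000 random lists matched on mean expression. Sequence matches to the eCLIP adapter used 8-mers of its constant part of 22 nt and 4 inline barcodes, written from general knowledge of the method and not from the labels. Control windows for these lay 200 nt from each peak. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, pyranges 0.1.4 and matplotlib 3.10.9 was used for the peaks, summaries and figures.

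The gene test was tested on simulated data with 200 changed genes among 17622, over 10 runs. At a 2-fold change it recovered 74.9% of them in the pachytene contrast and 75.3% in the round spermatid contrast. False genes made up 78.8% of the pachytene calls and 1.79% of the round spermatid calls. The overlap measure returned 21.1% for a planted overlap of 20%, and the seed search counted 49 windows where 40 of 2000 held a planted site. Alternatives covered the pseudocount, the minimum TPM, the libraries in the fit, a term for replicate number, each library left out in turn, thresholds, the list test, peak strength and the annotation order. Further alternatives were added after seeing the data: median-ratio scaling, leaving out the pseudogenes Gm12895 and Gm12896, a separate spread for each group, leaving out peaks with an adapter match, and random placement within exons. The ChIP samples and the eCLIP of pachytene spermatocytes and round spermatids were not analysed here, because the deposited table and lists used hold no values for them.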

Results

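RNA-seq and eCLIP, which maps the RNA bound by a protein, were used to follow AGO2, an Argonaute protein that carries microRNAs to their targets, in mouse spermatogenic cells. The RNA-seq covered pachytene spermatocytes, which are in meiotic prophase, and round spermatids, the haploid cells formed after meiosis. There were 2 control and 2 cKO libraries of pachytene spermatocytes, and 3 control and 3 cKO libraries of round spermatids. The eCLIP data were 2 peak lists, 1 per replicate, from the cytoplasm of whole adult testis of wild-type mice. TPM keep no read totals and the peak lists give no counts, so the depth of each sample is unknown. Round spermatid libraries of a group resembled one another (Pearson's r across genes 0.991 to 0.996) more than pachytene libraries of a group did (0.962 for control and 0.974 for cKO). Pachytene control and cKO replicate 2 were closer to each other (0.984) than to the other replicate of their genotype. Pachytene control replicate 1 was slightly closer to cKO replicate 1 (0.964), while cKO replicate 1 was closest to cKO replicate 2. The median SD within a group was 0.29 (log2) in pachytene spermatocytes and 0.13 in round spermatids. The pseudogenes Gm12895 and Gm12896 together took 20.5% to 34.6% of TPM in each library.

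The deleted gene itself comes first, since its level bears on the labels. Ago2 (ENSMUSG00000036698, mm10 chromosome 15, 73095844 to 73184935, minus strand) averaged 14.8 ± 0.523 TPM (SD, n = 2) in pachytene control libraries and 9.63 ± 2.43 TPM (SD, n = 2) in the libraries labelled cKO. Both cKO libraries lay below both control libraries, with a log2 fold change of −0.59 (SE 0.18) that did not pass the test (limma adjusted p = 0.0558). In round spermatids Ago2 stood at 4.00 ± 0.392 TPM in control and 4.39 ± 0.177 TPM in the libraries labelled cKO (SD, n = 3), a log2 fold change of 0.11 (SE 0.14, limma adjusted p = 1). The round spermatid libraries labelled cKO thus held no less Ago2 transcript than their controls. TPM cover whole transcripts, so they cannot show the loss of single exons, and the labels do not say which exons were deleted. The pachytene change passed the test at −0.61 (limma adjusted p = 0.0427) without Gm12895 and Gm12896, and was −0.82 without pachytene cKO replicate 2. With pachytene libraries alone, or with a separate spread for each group, 0 genes passed, so Ago2 did not either. The median change of all genes in this contrast was −0.25 (log2). The mean of the AGO and microRNA list was −0.53, so the fall does not single out Ago2.

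**Figure D1:**
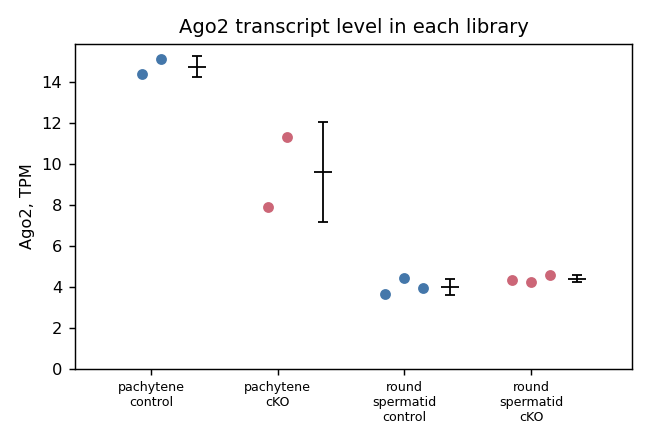
Ago2 expression in TPM (y axis) in each of the 10 libraries by stage and genotype (x axis), with points for libraries and bars for the mean ± SD. The pachytene cKO libraries, at 7.90 and 11.3 TPM, lie below the controls, and the round spermatid groups overlap.

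The pachytene comparison asks which transcripts differ between cKO and control spermatocytes. Prm1, which encodes a protamine that packs sperm DNA, rose from 11333 ± 3306 TPM in control to 27020 ± 6357 TPM in cKO (SD, n = 2). Ddx4, a germ-cell RNA helicase of the piRNA pathway, fell from 96.4 ± 31.3 to 33.0 ± 13.5 TPM (SD, n = 2). At an adjusted p under 0.05, limma called 2095 genes, 422 higher and 1673 lower in cKO. The split depends on scaling: the median of all genes was −0.25 (log2) in TPM and −0.08 after median-ratio scaling, which called 966 genes, 836 higher and 130 lower, 552 of them shared. Changes below are therefore best read against that median.

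In the list of elongating spermatid and chromatin condensation genes, 9 of 21 tested members rose over all genes tested, and 14 rose and 0 fell adjusted over the list alone. The mean change was 0.77 (log2; camera adjusted p = 7.2e-15), and the adjusted p was 0.586 with an estimated correlation and 0.2 with fry. Members with the smallest p were Tex37 (log2 1.12, SE 0.21), Oaz3 (1.17, SE 0.27), Gapdhs (1.13, SE 0.27) and Spata3 (1.21, SE 0.30), each with an adjusted p between 0.0335 and 0.0392. Prm1, Prm2 and Tnp1, protamine and transition protein genes, rose by 1.26, 1.38 and 1.32 (adjusted p = 0.0424, 0.0464 and 0.0401), and were chosen after their values were seen. The summed TPM of the list was 35609 and 62314 in the control libraries and 117800 and 102500 in the cKO libraries. Of 25 round spermatid markers, 4 rose (Tssk6, Spert, Actl9 and Tssk3, log2 0.71 to 1.29) and 0 fell over all genes tested, 5 rose and 2 fell adjusted over the list alone, and the list as a whole was not called (adjusted p = 0.27). The mean change of the round spermatid list was 0.33 without pachytene control replicate 2. Its mean log2(TPM + 1) was 6.11 and 6.99 in the control and 6.28 and 6.59 in the cKO libraries. Leaving out control replicate 1 thus moves it the other way, to below 0. The mean of the elongating spermatid list stayed above 0 after median-ratio scaling, at 1.00, and its call held with any library left out, but its size moved to 0.33 without pachytene control replicate 1 and to 1.22 without control replicate 2.

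**Figure D2:**
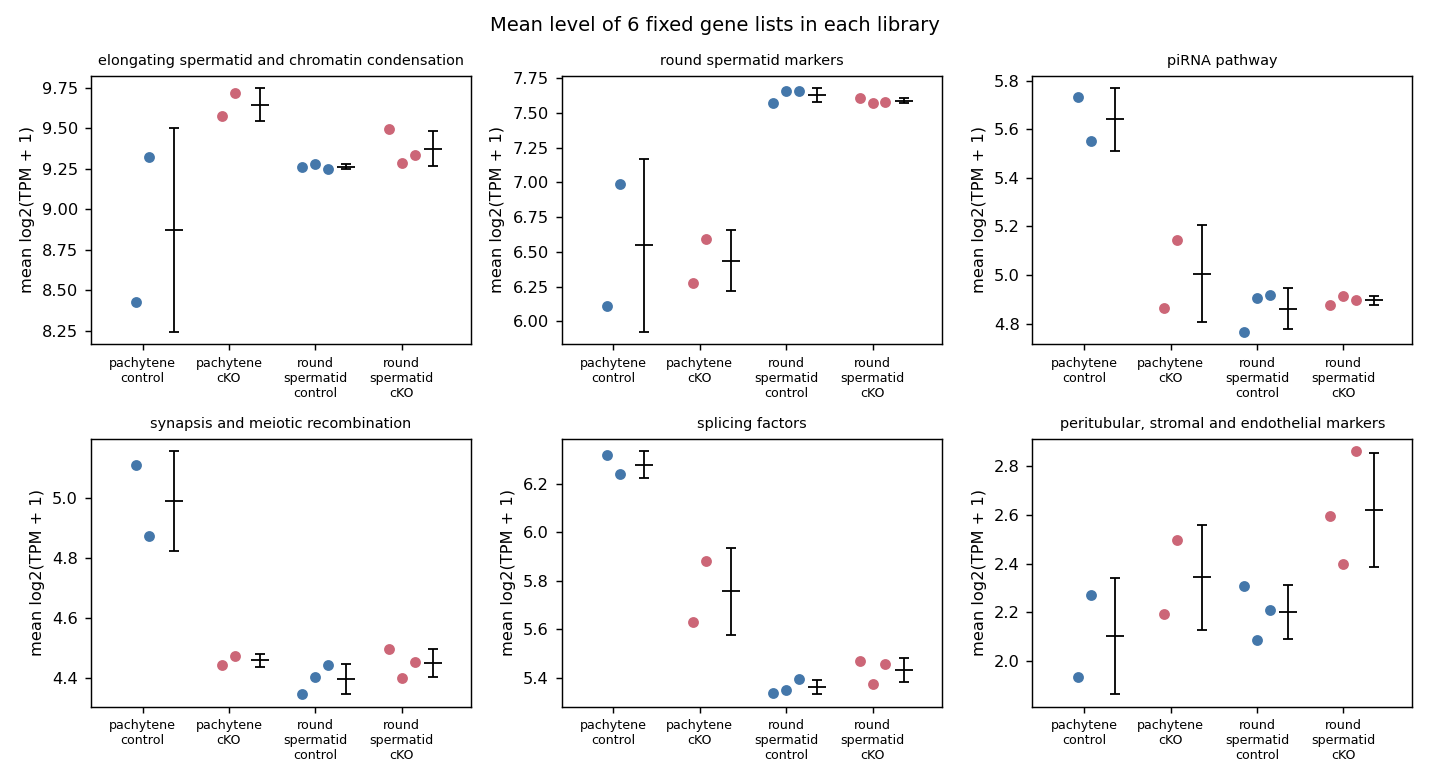
Mean log2(TPM + 1) of the members of 6 gene lists (y axes, which do not start at 0) in each of the 10 libraries by stage and genotype (x axes), with points for libraries and bars for the mean ± SD. Elongating spermatid genes reach 9.57 and 9.72 in the pachytene cKO libraries against 8.43 and 9.32 in the controls, and the piRNA, synapsis and splicing lists lie lower in pachytene cKO.

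Camera placed 4 lists lower in cKO: splicing factors, piRNA, synapsis and recombination, and AGO and microRNA genes. Most members did not pass over all genes tested, and none of the 4 calls held with an estimated correlation. In control cells these lists also had means below 0 in round spermatids against pachytene spermatocytes (−0.92, −0.78, −0.59 and −0.40). Spermatid RNA in the cKO libraries could therefore lower them too, which was not tested. Splicing factor genes had 9 of 30 members lower over all genes tested and 22 lower adjusted over the list alone, with a mean of −0.52 (camera adjusted p = 1.8e-05). For this list the adjusted p was 0.586 with an estimated correlation, and Srsf3, Srsf7, Hnrnpa1 and Hnrnpc fell by 0.72, 0.68, 0.68 and 0.73. In the piRNA pathway, which silences transposons and cleaves other germ-line transcripts, 6 of 22 genes fell over all genes tested and 15 adjusted over the list alone (mean −0.64, camera adjusted p = 0.000523). Its adjusted p was 0.652 with an estimated correlation, and besides Ddx4 its members Tdrd7, Tdrkh and Tdrd5 fell by 0.76, 0.79 and 0.93. Synapsis and meiotic recombination genes had 8 of 32 members lower over all genes tested, and 1 higher and 21 lower adjusted over the list alone (mean −0.53, camera adjusted p = 0.000523). With an estimated correlation their adjusted p was 0.586. Spo11, which makes the breaks that start recombination, fell by 0.91, and Sycp3 of the synaptonemal complex, Tex12 and Spata22 by 0.75, 0.96 and 0.77. The list of AGO proteins and microRNA machinery had 4 of 18 members lower over all genes tested (Tnrc6a, Dgcr8, Ddx6 and Prkra, log2 −0.81 to −0.65) and 11 adjusted over the list alone. Its mean was −0.53 (camera adjusted p = 0.00708; adjusted p = 0.586 with an estimated correlation). Ago1, Ago3, Ago4 and Dicer1 had log2 fold changes of −0.40, −0.41, −0.48 and −0.82 and did not pass the test (adjusted p = 0.0612 to 0.244). After median-ratio scaling these 4 lists kept means below 0, at −0.30 for splicing, −0.42 for piRNA, −0.32 for synapsis and −0.33 for AGO and microRNA genes. The call of the piRNA, synapsis and AGO lists ended without pachytene control replicate 1, at adjusted p = 0.108, 0.21 and 0.225.

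Markers of other testis cells differed between the pachytene libraries too. Leydig cell markers, genes of the steroid-making cells outside the tubules, added up to 1844 and 5031 TPM in the control libraries and 1959 and 2589 TPM in cKO. Their list was not called (0 of 14 members passed, camera adjusted p = 0.861), except lower without pachytene control replicate 1 (mean −1.08, adjusted p = 0.00116). Sertoli cell markers (mean 0.19, 0 of 16 members called, camera adjusted p = 0.00207) and peritubular, stromal and endothelial markers (mean 0.24, 1 of 15 members higher, Vwf, camera adjusted p = 0.000276) were called higher as lists. Each of these had an adjusted p of 0.586 with an estimated correlation. Macrophage markers (mean 0.16, 0 of 15 members called) had a camera adjusted p of 0.0114, and an adjusted p of 0.973 with an estimated correlation. These 3 means depend on single libraries. Without pachytene control replicate 1, control replicate 2, cKO replicate 1 and cKO replicate 2 they were 0.07, 0.31, −0.01 and 0.39 for Sertoli, 0.07, 0.41, 0.40 and 0.09 for peritubular, and −0.01, 0.34, 0.44 and −0.12 for macrophage markers. The Sertoli call ended without control replicate 2 (adjusted p = 0.0529) and without cKO replicate 1 (adjusted p = 0.485). The macrophage call ended without control replicate 2 (adjusted p = 0.232), without cKO replicate 2 (adjusted p = 0.143) and after median-ratio scaling (adjusted p = 0.0626). Mitochondrial transcripts took 1.63% of TPM in pachytene cKO replicate 2 and 0.431% to 0.916% in the other pachytene libraries.

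Sex-linked genes and the remaining lists gave the following. Of 366 Y-linked genes, 8 rose and 12 fell over all genes tested, and 4 rose and 4 fell adjusted over the list alone. Their mean was −0.14 while camera placed them above other genes (adjusted p = 0.0206; adjusted p = 0.973 with an estimated correlation). That call ended after median-ratio scaling (adjusted p = 0.904), without pachytene control replicate 1 (adjusted p = 0.85), without cKO replicate 2 (adjusted p = 0.143) and without Gm12895 and Gm12896 (adjusted p = 0.0665). The Y mean was −0.40 and 0.12 without pachytene control replicate 1 and 2, and 0.02 and −0.30 without cKO replicate 1 and 2. Of 743 X-linked genes 33 rose and 30 fell (31 and 17 adjusted over the list alone), and the list was not called (adjusted p = 0.144), except without cKO replicate 2 (adjusted p = 0.00975). Pachytene markers had a mean of −0.52, with 3 of 20 members lower over all genes tested (Tdrd5, Hspa2 and Tbpl1) and 11 adjusted over the list alone. Their list was not called (adjusted p = 0.0998), and was called without Gm12895 and Gm12896 (adjusted p = 0.0414) and without cKO replicate 2 (mean −0.79, adjusted p = 0.0048), while the mean was −0.25 without cKO replicate 1. Also not called were ribosomal protein genes (9 of 82 lower, 0 adjusted over the list alone; 0.0754), and sperm head genes (2 higher and 3 lower of 40, and 3 and 9 adjusted over the list alone; 0.81). The same held for flagellum genes (Tekt1, Rsph9, Tekt4 and Tekt3 lower of 41; 0.898), spermatogonia markers (Id4 lower of 18; 0.545), and p53 targets (Bbc3 higher and Mdm2 lower of 14; 0.963). Adjusted over the list alone these had 4 lower, 0 lower, and 1 higher and 2 lower. With 1 library left out, ribosomal protein genes were called lower without pachytene control replicate 2 (mean −0.46, adjusted p = 2.2e-06) and cKO replicate 1 (−0.45, 3.1e-07), and flagellum genes higher without cKO replicate 1 (0.10, 0.0445). Spermatogonia markers (mean −0.48) were placed above other genes without pachytene control replicate 1 (−0.07, 0.0488), and called lower without control replicate 2 (−0.88, 0.00457) and cKO replicate 1 (−0.74, 0.0205). Translational control genes (2 of 23 lower, 4 adjusted over the list alone; 0.75) and interferon-stimulated genes (0 of 10; 0.654) were not called, and red blood cell genes, with 4 members, were not tested as a list. For round spermatid markers, flagellum, interferon-stimulated and X-linked genes the mean was below 0 while the test direction was up, and after median-ratio scaling these means were 0.11, 0.01, 0.02 and 0.01.

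Genes named by the rule in pachytene cKO included Hmga1b, a chromatin protein gene (log2 2.38, SE 0.45, adjusted p = 0.0344; 3.24 ± 3.45 to 17.2 ± 3.43 TPM, SD, n = 2). Tma7-ps, Ccl8, Ear-ps8, Calml4, Defb11, H2al1n, Pou6f2, Tex13c3, Neurl1a, Cby3 and Azin2 rose by 1.45 to 2.20. Of the genes named by the rule Ddx4 fell most (log2 −1.54, SE 0.29, adjusted p = 0.0335), and Moap1, Tgif2lx1, Defb14, Kpna2, Fbxo5, H3f3c, Cct8, Trim13, Nuf2, Zfp438 and Psmg4 had log2 fold changes from −1.38 to −1.11. Among these, Kpna2 encodes a nuclear import receptor (178 ± 17.5 to 77.8 ± 27.8 TPM), Cct8 a chaperonin subunit (92.7 and 119 TPM in the control and 36.1 and 59.5 TPM in the cKO libraries) and Nuf2 a kinetochore protein (48.5 ± 1.76 to 22.7 ± 9.54 TPM; SD, n = 2). All 24 kept their direction in every fit with 1 library left out, which the rule of no overlap between cKO and control libraries fixed in advance. Of their calls 0 remained without round spermatid control replicate 1, 2 or 3 or cKO replicate 3, 4 without round spermatid cKO replicate 1 or 2, and 1 without pachytene cKO replicate 1, against 19, 24 and 20 without pachytene control replicate 1, control replicate 2 and cKO replicate 2.

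The pachytene count rests on a spread borrowed from the round spermatid libraries: with pachytene libraries alone limma called 0 genes (1489 at an unadjusted p under 0.05), and with a separate spread for each group it called 0 (1604 at an unadjusted p under 0.05). It was 20 without pachytene cKO replicate 1, 5407 without control replicate 2, 1, 1 and 8 without round spermatid control replicate 1, 2 and 3, 18, 17 and 5 without round spermatid cKO replicate 1, 2 and 3, and 505 with no minimum TPM. On simulated data with 200 changed genes, a mean of 627.4 of 796.3 genes called in this contrast were false (78.8%). That share depends on the number of changed genes and need not hold for the 2095 calls. Since 0 genes were called with pachytene libraries alone, single pachytene calls still carry little weight.

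In round spermatids the comparison asks the same of haploid cells, and few genes were called in the fit where all libraries share 1 spread. Rpl10a, a ribosomal protein gene, rose 5.11-fold from 15.2 ± 2.98 to 77.6 ± 11.6 TPM (SD, n = 3; log2 2.28, SE 0.23, limma adjusted p = 0.00254), and Churc1, a zinc finger gene, rose from 12.9 to 15.9 TPM in the 3 control libraries to 42.0 to 45.8 TPM in the 3 cKO libraries (log2 1.55, SE 0.14, adjusted p = 0.0013). Dennd3, a gene for a Rab exchange factor on chromosome 15 (73512560 to 73572242), fell from 6.52 to 7.88 TPM in the 3 control libraries to 0.965 to 1.91 TPM in the 3 cKO libraries (log2 −1.70, SE 0.20, adjusted p = 0.00759). Limma called 38 genes, 19 higher and 19 lower. Of the 38, 15 lie on the Y chromosome and 7 on chromosome 15, and 21 have a Gm-number or Rik symbol.

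The other named genes that rose were Tapbpl (log2 1.36), BC049730 (1.34), Fam173b (2.34 ± 0.215 to 6.60 ± 0.605 TPM, SD, n = 3), Rnf138rt1 (1.11), Suox (0.98), Panx1 (0.89), Wdr34 (0.87), Ncaph2 (0.78) and March5 (0.67). The named genes that fell were Fcmr (−1.04), Ifi209 (−0.90), Dap (−0.86) and Dock5 (−0.74). Rnf138rt1, on the X chromosome, went from 16.2 ± 0.138 to 36.0 ± 0.591 TPM (SD, n = 3), and was also called higher in pachytene cKO (15.5 ± 4.91 to 41.2 ± 3.74 TPM, SD, n = 2). Suox, which encodes sulfite oxidase, stood at 3.10 ± 0.256 and 7.11 ± 1.03 TPM, and Ifi209, an interferon-inducible gene, at 9.13 ± 0.284 and 4.41 ± 0.14 TPM (SD, n = 3). Of the 16 named genes all kept their direction with any library left out, which the rule of no overlap fixed in advance. Rpl10a and Churc1 also kept their call. The number of the 16 still called was 2, 2 and 4 without round spermatid control replicate 1, 2 and 3, and 3, 4 and 3 without cKO replicate 1, 2 and 3, against 14 without pachytene cKO replicate 1 or 2. The count of 38 became 12 and 17 without control replicate 1 and 2, 16, 16 and 18 without cKO replicate 1, 2 and 3, and 74 without pachytene control replicate 1 or 2. With round spermatid libraries alone it was 263, 38 of them shared, and with a separate spread for each group it was 569. The shared spread takes in the pachytene libraries, whose median SD was 0.29 (log2) against 0.13 in round spermatids. In pachytene spermatocytes the same settings called 0 and 0 genes, so the counts of the main fit do not rank the stages.

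**Figure D3:**
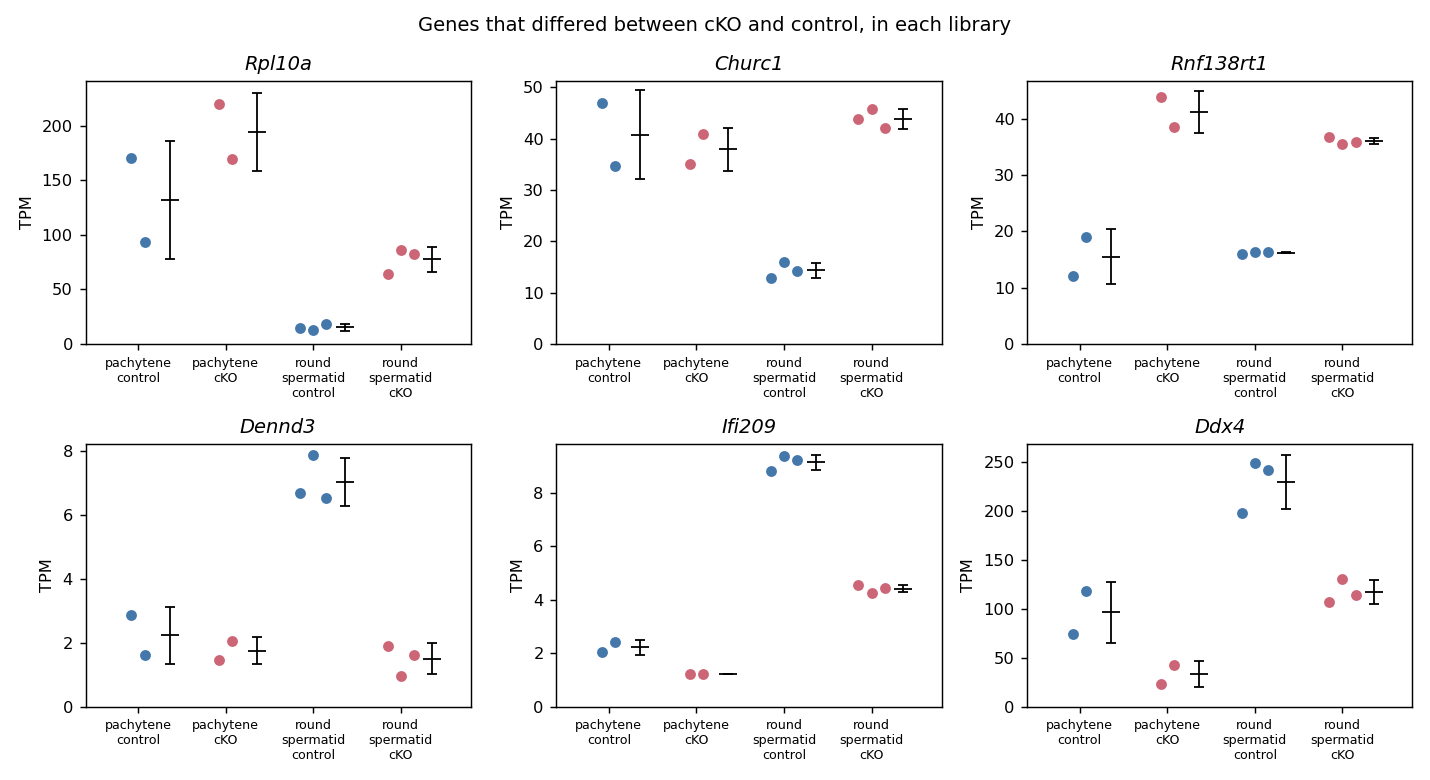
Expression in TPM (y axes from 0) of Rpl10a, Churc1, Rnf138rt1, Dennd3, Ifi209 and Ddx4 in each of the 10 libraries by stage and genotype (x axes), with points for libraries and bars for the mean ± SD. Rpl10a lies at 12.8 to 18.5 TPM in round spermatid controls and at 64.4 to 86.0 TPM in round spermatid cKO.

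Of the 20 lists, 2 were called in round spermatids. Peritubular, stromal and endothelial markers were higher in cKO (mean 0.42, camera adjusted p = 3.0e-06; adjusted p = 0.586 with an estimated correlation). No member passed over all genes tested, and 4 of 15 were higher adjusted over the list alone: Col3a1, Myh11, Acta2 and Tagln, genes of connective tissue and smooth muscle, at 0.83, 0.63, 0.87 and 0.51. The summed TPM of these markers was 58.0 to 72.1 in control and 79.8 to 127 in cKO libraries. X-linked genes were the other list (mean 0.11, 525 of 743 above 0, camera adjusted p = 0.00546; adjusted p = 0.973 with an estimated correlation), and its call ended without round spermatid control replicate 2 (adjusted p = 0.09). The meiotic, piRNA, splicing, spermatid and microRNA lists were not called, and the adjusted p of all 18 other lists lay between 0.105 and 0.934. Of these, 3 were called without control replicate 1 and without cKO replicate 2: pachytene markers lower (adjusted p = 0.0189 and 0.0161; means −0.12 and −0.08), flagellum genes lower (0.00404 and 0.00274; −0.11 and −0.06) and macrophage markers higher (0.00158 and 0.000531; 0.39 and 0.49). After median-ratio scaling round spermatid markers (mean −0.09) and flagellum genes (mean −0.07) were called lower, each at an adjusted p of 0.046. Of the Y-linked genes 4 rose and 11 fell over all genes tested, and 14 rose and 19 fell adjusted over the list alone. Ago1, Ago3, Ago4, Dicer1 and Tnrc6a had log2 fold changes between −0.02 and 0.27, each with an adjusted p of 1. The mean was above 0 and the test direction down for sperm head, spermatogonia, translational control and ribosomal protein genes, and for Y-linked genes the median was 0.09 and the direction down.

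Whether the cKO effect differs between the stages was tested directly. The effect in round spermatids minus that in pachytene spermatocytes passed the test for 11 genes, 5 above and 6 below 0, and the 8 with the smallest adjusted p are pseudogenes or Y-linked gene copies. Gm12191, a processed pseudogene on chromosome 11 (49678710 to 49679057), had 0.914 ± 0.505 TPM in round spermatid control and 221 ± 27.9 TPM in round spermatid cKO (SD, n = 3), with 85.8 to 182 TPM in all pachytene libraries (difference of effects 6.85, SE 0.43, adjusted p = 0.000356). Gm20924, on the Y chromosome, had 8.74 ± 2.55 TPM in pachytene control and 0.00381 ± 0.00335 TPM in pachytene cKO (SD, n = 2), with 5.47 to 12.7 TPM in all round spermatid libraries (difference 3.64, SE 0.38, adjusted p = 0.00665). The Y-linked Gm21409, Gm21728, Gm21333, Gm21658, Gm20849 and Gm20864 had differences from −2.78 to −1.82, with means of 3.24 to 7.44 TPM in round spermatid control and 0.0155 to 0.29 TPM in round spermatid cKO. Reads from Y-linked copies and processed pseudogenes can match several genes, so which copy they come from is uncertain. The count of 11 was 41 and 3257 without pachytene control replicate 1 and 2, 22 and 438 without pachytene cKO replicate 1 and 2, 7 without round spermatid control replicate 1 or 2, 6 without round spermatid cKO replicate 1, and 1 with a separate spread for each group.

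Across the 17622 genes the effects in the 2 stages correlated with Pearson's r of 0.19 and Spearman's rho of 0.191, where genes are not independent replicates. Of the genes called, 7 were called in both stages, all in the same direction, against 2.26 expected: Tapbpl, Rnf138rt1, Panx1 and Angptl2 rose, and Ifi209, Fcmr and Dock5 fell. Angptl2 lies outside the naming rule and was chosen after its values were seen. Without round spermatid cKO replicate 1 the r was 0.0853 and the rho 0.0352.

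The contrast of round spermatids with pachytene spermatocytes in control cells compares the stages, but Leydig and Sertoli cell markers differed too, so it mixes stage with the make-up of the preparations. None of its list calls held with an estimated correlation, where the smallest adjusted p was 0.518. Limma called 12145 genes, 7010 higher and 5135 lower, and after median-ratio scaling 6133 higher and 6234 lower, with the median of all genes moving from 0.19 to −0.02. Y-linked genes were higher (297 of 366 called higher and 5 lower, mean 1.38, camera adjusted p = 3.7e-15), as were round spermatid markers (19 of 25 higher and 1 lower, mean 1.08, adjusted p = 0.00195). Spata31 and Izumo3, of the latter list, rose by 3.10 and 2.27. Flagellum genes (24 of 41 higher and 1 lower, mean 0.82, adjusted p = 0.0133) and X-linked genes (357 of 743 higher and 156 lower, mean 0.40, adjusted p = 0.0307) were also called, the latter not without pachytene control replicate 2 (adjusted p = 0.0608), round spermatid control replicate 1 (adjusted p = 0.0506) or Gm12895 and Gm12896 (adjusted p = 0.0993). Without pachytene control replicate 1 the means of round spermatid markers and flagellum genes were 0.64 and 0.51. Adjusted over the list alone the counts higher and lower were 303 and 5 for Y, 19 and 1 for spermatid, 22 and 1 for flagellum and 357 and 156 for X.

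Genes lower in round spermatids included the piRNA gene Piwil1 (log2 −3.05) and the recombination gene Ccnb1ip1 (−4.62), and Ago2 itself (−1.66) and Tnrc6a (−2.16). As lists, ribosomal protein genes (62 of 82 lower and 5 higher, mean −0.99, camera adjusted p = 2.2e-11), splicing factors (23 of 30 lower, −0.92, 1.4e-07) and piRNA genes (14 of 22 lower and 7 higher, −0.78, 0.0111) were lower. So were synapsis genes (18 of 32 lower and 6 higher, −0.59, 0.00496), spermatogonia markers (12 of 18 lower and 3 higher, −1.14, or −0.74 without pachytene control replicate 1, 0.00322) and Sertoli cell markers (9 of 16 lower and 2 higher, −1.05, 0.0116). Adjusted over the list alone 62, 24, 14, 18, 15 and 9 were lower in these lists. Leydig cell markers had 13 of 14 members lower (13 adjusted over the list alone; mean −4.06, adjusted p = 2.8e-08), with 48.6 to 81.9 summed TPM in round spermatid libraries against 1844 to 5031 in pachytene libraries. Insl3, a Leydig cell hormone, was at 2239 ± 1546 TPM (SD, n = 2) in pachytene control and 10.1 ± 3.10 TPM (SD, n = 3) in round spermatid control. All these lists kept their sign after median-ratio scaling. The other 9 lists were not called between stages (camera adjusted p = 0.0505 to 0.983), but AGO genes were called lower after median-ratio scaling (0.0229) and sperm head genes higher without Gm12895 and Gm12896 (0.046). AGO genes (adjusted p = 0.0505) were also called in every fit with 1 library left out (0.0467 to 0.0499, and 0.028 without pachytene control replicate 2) except those without pachytene or round spermatid control replicate 1. Elongating spermatid genes (mean 0.83, adjusted p = 0.0162) and sperm head genes (0.73, 0.0249) were called higher without pachytene control replicate 2. In this contrast pachytene markers and interferon-stimulated genes had means above 0 with the test direction down.

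Single genes with the largest stage differences were Lars2, a mitochondrial leucyl-tRNA synthetase gene (2645 ± 421 to 3.84 ± 0.346 TPM, log2 −9.09), and Tmem38b (3399 ± 1658 to 9.02 ± 0.63 TPM, log2 −8.32; SD, n = 2 and n = 3). Rps12-ps3, Rps6-ps4 and Hist1h4m averaged 257, 225 and 267 TPM in pachytene control and are listed at 0 in all 3 round spermatid controls. Hist1h4m varied between the pachytene controls (505 and 28.7 TPM) and lost its call without control replicate 1 (adjusted p = 0.0648). AC148174.4, Olfr1509, Csnka2ip, Ms4a14, Krt80 and AC140413.4 rose by 3.41 to 4.02.

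The eCLIP lists ask where AGO2 sits on RNA in testis cytoplasm. The first list holds 65011 peaks with a median width of 20 nt and a median log2 enrichment of 6.75, in 11976 genes, and the second 21346 peaks of 14 nt and 5.70, in 6365 genes. Of the first list 19.7% of peaks (Wilson 95% interval 19.4 to 20.04) lay in CDS, 9.25% (9.03 to 9.47) in 3' UTRs and 40.1% (39.8 to 40.5) in introns. For the second list these were 28.7% (28.1 to 29.3), 10.48% (10.1 to 10.9) and 29.2% (28.6 to 29.9). A further 23.7% and 22.9% lay in no annotated gene. Of peaks in introns or no gene, 8.48% of the first list held the adapter barcode X2A and 20.1% of the second held X2B. Control windows held them at 0.926% and 1.30%, and CDS peaks at 0.764% and 4.70%. These were the most enriched barcodes of each list, so the intron shares need not show where AGO2 sits. Peaks in the 2 lists overlapped for 4.45% of the first list and 13.6% of the second. At random positions this was 0.379% and 1.17% (permutation p = 0.0099, the smallest that 100 draws can give). Those positions lay in the same genes or, for peaks in no gene, anywhere on the same chromosome. Among stronger peaks, with at least 2 times the lowest enrichment kept, CDS held 13.4% and 19.7%, and introns 45.6% and 35.8%.

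The 10 genes with the strongest shared peaks were Gm12153, Pla2g1b, Gnaq, Adra1b, Slc14a2, Lrrc8d, its antisense transcript Lrrc8dos at the same peak, Cadps2, Tmem132c and Camkmt. All of these peaks lay in introns, with a lower log2 enrichment of 9.73 to 12.5 over the 2 lists, and the strongest was at 44009628 to 44009635 on chromosome 11 in Gm12153. Each holds or borders a run of 9 to 12 nt that matches the library adapter. The share of peak windows with an adapter 8-mer was 3.63% in the first list and 6.75% in the second, against 0.774% and 0.799% of control windows. It was 23.9% and 24.0% among shared peaks and 48% and 60% among the strongest 100 shared peaks. In 3' UTRs it was 1.20% and 1.70%, against 0.582% and 0.671% of control windows. Ago2 itself held 3 peaks in the first list and 0 in the second.

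**Figure D4:**
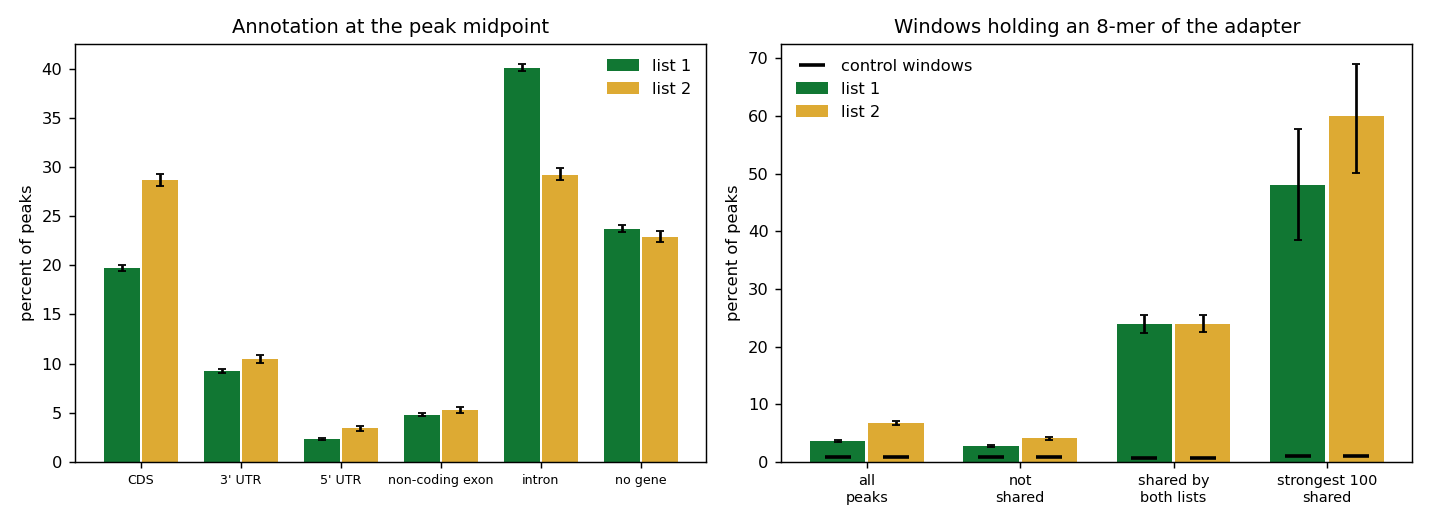
Left, percent of peaks (y axis) by annotation (x axis) in each eCLIP list, with Wilson 95% intervals. Right, percent of peak windows that hold an 8-mer of the library adapter (y axis) among all, unshared, shared and the strongest 100 shared peaks, with black marks for control windows: the share rises from 3.63% and 6.75% of all peaks to 48% and 60% of the strongest shared ones.

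Of the 12 microRNA seed matches searched in 3' UTR peaks, 1 was more frequent than in control windows of the same UTRs, and in 1 list. The match to miR-202-5p, a microRNA abundant in germ cells, was in 28 of 5846 windows of the first list (0.479%, Wilson 95% interval 0.332 to 0.691) against 0.222% of control windows (Fisher's exact test, two-sided, adjusted p = 0.0142). In the second list it was in 8 of 2186 windows (0.366% against 0.293%, adjusted p = 0.684), and none of the 12 passed. The call for miR-202-5p ended without the extension by 20 nt (adjusted p = 0.908), with stronger peaks (0.782) and without peaks that match the adapter (0.0522). In the last setting all 28 windows with the site remained, of 5774. The ratio to control windows was 1.94 in place of 2.15, so that call ended by a small margin. Control windows were drawn anew in each setting. The site was in 0.480% of windows of stronger peaks against 0.353% of their controls, and in 0.485% against 0.249% without adapter matches. The call thus depends on the draw of control windows too. The other 11 matches, let-7 among them, each had an adjusted p of 0.905 in the first list.

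Genes bound in both lists in CDS or 3' UTR were set against the RNA changes, to ask whether bound transcripts move in cKO. The 2300 tested targets had a mean log2 change of −0.30 in pachytene spermatocytes (camera adjusted p = 0.0035; adjusted p = 0.737 with an estimated correlation). Their median of −0.36 lay at percentile 0.21 of 10000 lists matched on expression, whose median was −0.34 (95% of them from −0.36 to −0.32). That percentile was 18.3 with stronger peaks and 45.1 with 3' UTR peaks only. In round spermatids the targets had a mean of 0.05 (camera adjusted p = 0.394, and 0.8 with an estimated correlation). Their median of 0.04 lay at percentile 99.98 of the matched lists, whose median was 0.03. This round spermatid percentile was 100 with stronger peaks and 99.98 with 3' UTR peaks only. The matched lists are drawn over genes, so the percentiles of both stages measure no spread between libraries. The pachytene call ended for the 935 genes with shared 3' UTR peaks (mean −0.27, adjusted p = 0.103) and without pachytene control replicate 1 (mean −0.35, adjusted p = 0.299).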

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

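The tests of adapter barcodes, of chromosome 15, of a different background, of levels above round spermatids, of elongating spermatids alone and of a common factor, and the setting without Gm12895 and Gm12896, were chosen only after the results were seen.

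The cKO effect differed between the stages in a direct test for 11 genes, and 8 of these are given with the round spermatid effect minus the pachytene effect (log2). The values were 6.85 for Gm12191, 3.64 for Gm20924, −2.78 for Gm21409, −2.23 for Gm21728, −2.32 for Gm21333, −1.82 for Gm21658, −2.003 for Gm20849 and −2.29 for Gm20864. Of these 8, 7 stayed past the threshold without round spermatid control replicate 1 or 2 or cKO replicate 2, and 6 without cKO replicate 1, while 4 did so with a pseudocount of 0.1 and 1 with a separate spread for each group.

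The same test differed between stages for 9 gene lists by camera, for 4 by fry, and for 0 by camera with an estimated correlation. In the last setting these 9 lists had adjusted p from 0.391 to 0.924, and 0 of all 20 lists had an unadjusted p under 0.05. The mean differences were 0.59 for AGO proteins and microRNA machinery, 0.67 for the piRNA pathway, 0.58 for synapsis genes, 0.60 for splicing factors, 0.35 for ribosomal proteins, −0.66 for elongating spermatid genes and −0.09 for Sertoli cell markers. For round spermatid markers (0.0709) and Y-linked genes (0.14) the mean was above 0 and the test direction down, and after median-ratio scaling the means were −0.21 and −0.02. That scaling moved the median of all genes from 0.29 to 0.07, and the AGO, piRNA, synapsis and splicing lists to 0.33, 0.40, 0.33 and 0.32, above the median. Some of these means depend on single libraries. Without pachytene control replicate 1, control replicate 2, cKO replicate 1 and cKO replicate 2 they were 0.51, −0.37, −0.08 and 0.23 for round spermatid markers, 0.40, −0.12, −0.02 and 0.30 for Y-linked genes, and 0.03, −0.21, 0.11 and −0.29 for Sertoli cell markers. The elongating spermatid mean was −0.22 and −1.11 without pachytene control replicate 1 and 2, and the ribosomal mean 0.19 and 0.21 without pachytene control replicate 1 and cKO replicate 2. The round spermatid mean was 0.04 without round spermatid control replicate 1, and the Sertoli mean −0.05 without round spermatid cKO replicate 2. Without pachytene control replicate 1 the calls of the AGO, piRNA, synapsis, round spermatid, ribosomal and Y lists ended (adjusted p = 0.172, 0.0592, 0.172, 0.31, 0.0592 and 0.31). The Sertoli call ended without pachytene control replicate 2 (0.0895) or cKO replicate 1 (0.685), and the round spermatid call without pachytene cKO replicate 2 (0.142) or round spermatid cKO replicate 1 (0.063). The ribosomal call also ended without pachytene cKO replicate 2 (0.191), round spermatid control replicate 1 or 2 (0.0706, 0.0512) and round spermatid cKO replicate 2 or 3 (0.215, 0.121). The ribosomal and Y calls ended after median-ratio scaling (0.618 and 0.727), and the ribosomal and round spermatid calls without Gm12895 and Gm12896 (0.0878 and 0.0902). Calls were gained by spermatogonia markers without pachytene control replicate 1 or 2 or cKO replicate 1 (0.0103, 0.0069 and 0.0398), Leydig cell markers without pachytene control replicate 1 (0.000113), flagellum genes without pachytene cKO replicate 1 (0.00526) and pachytene markers without pachytene cKO replicate 2 (0.00774). Macrophage markers gained a call without pachytene control replicate 1 (0.0199), pachytene cKO replicate 1 (0.0292), round spermatid control replicate 2 or 3 (0.0446, 0.0431) and round spermatid cKO replicate 3 (0.00948).

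In both eCLIP lists, 3.63% and 6.75% of peaks, and 23.9% and 23.96% of the shared ones, lie at genomic sequences that match the constant part of the library adapter. Base composition alone is argued against. Adapter 8-mers read backwards were 1.16 and 1.25 times as frequent in peaks as in control windows of the first and second list, against 4.70 and 8.44 times for the adapter. Control windows held the backwards 8-mers at 1.91% and 1.78%, and those of the adapter at 0.774% and 0.799%. Reading backwards changes which bases are neighbours, so the test cannot decide on the frequency of base pairs in a row. Adapter sequence in the reads remains a candidate explanation, since of the 4 barcodes searched the first list was enriched above all for X2A (5.86% of peaks, 6.74 times, against 0.661 in the second list) and the second for X2B (12.6% of peaks, 10.9 times, against 1.06 in the first). Without the peaks that match the constant part the lists overlapped for 3.51% and 11.1%, above 0.38% and 1.21% at random positions, but peaks at the barcodes stay in this setting. No biological explanation was tested, since the lists come from 1 group.

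The 38 genes called in round spermatids gather on chromosomes Y (15 genes, 39.5% against 2.08% of tested genes) and 15, which carries Ago2. Chromosome 15 held 7 of them, 18.4% against 3.64% of tested genes (Fisher's exact test, p = 0.000385, and 0.0104 corrected over 27 chromosomes and scaffolds), so variants linked to the targeted Ago2 gene may account for part of the list. A different background of the control animals cannot be told apart from the cKO effect: of 24 called genes expressed in pachytene cells, 10 (41.7%) differed there by under 0.25 of the round spermatid difference, and 8 moved the same way by at least 0.5 of it. The 10 splits of the 6 libraries are too few for a share under 0.05; the real split called 38 genes and the highest other 1, and for gene lists the real split called 2 and the highest other 10, with all 10 splits calling at least as many lists as the real one. That highest split sets control replicates 1 and 2 with cKO replicate 2 against the rest, which points to a structure of the samples that was not tested, though no list was called with an estimated correlation, and an effect of the genotype in the labels stays open.

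Some transcripts of elongating spermatids, such as Prm1 and Tnp1, were higher in pachytene cKO: 9 of 21 listed genes passed over all genes tested, and the list's adjusted p was 0.586 with an estimated correlation. For 8 of the 21 (38.1%) both cKO libraries lay above all round spermatid and pachytene control libraries. Carry-over from round spermatids is argued against for 7 of these, Prm1 and Tnp1 among them, which lay above by 0.36 to 0.85 (log2). Oaz3 lay above by 0.01, within the spread of pachytene groups (0.29), and decides nothing. A factor common to all transcripts of a library is argued against by the median of all genes, which was −0.25 (log2) while the list's mean was 0.77. Median-ratio scaling (list mean 0.999) adds nothing to this, since a median below 0 fixed that direction. Leaving out Gm12895 and Gm12896 (0.763) decides nothing, as they held 25.1% of TPM in control and 24.8% in cKO. Carry-over of spermatid RNA in general, or from elongating spermatids alone, may explain the rise and cannot be told apart from a change in the spermatocytes: 90.5% of the list (19 of 21 genes) had a log2 change above 0, and the round spermatid markers (36%, 9 of 25, above 0, with 4 called higher and 0 lower) already stand at 63.7% of their round spermatid level in pachytene control, while the series has no library of elongating spermatids. Prm1 stood at 11333 TPM in pachytene control and 7220 TPM in round spermatid control, Tnp1 at 12897 and 6217 TPM, 1 of the 23 listed genes is in another list, all 21 tested are expressed in round spermatid controls, and the labels name no sort or gate.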

How the results depend on the processing

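Median-ratio scaling, the setting without Gm12895 and Gm12896, the separate spread, the setting without adapter matches and placement within exons were chosen only after the results were seen, and all other settings here were planned. Planned fits for counts (DESeq2 size factors in place of TMM, and the DESeq2 Wald test) were not run, because TPM are not counts, and the difference between stages has no value with only the libraries of the groups compared. Some list means changed sign: in pachytene cells that of macrophage markers went from 0.16 to −0.12 without cKO replicate 2. Depth limits every value in a way not measurable, since TPM and peak lists keep no read totals. Where an arm keeps 1 library, it is assumed to vary like the other groups.

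The pachytene count of 2095 genes was 1972 with a pseudocount of 0.1 and 2723 without Gm12895 and Gm12896, and moved to 505 with no minimum mean, 966 with median-ratio scaling and 4478 at adjusted p under 0.10. With that scaling 836 genes were higher and 130 lower, in place of 422 and 1673. Limma called 0 genes with only the pachytene libraries (1489 at unadjusted p under 0.05), 0 with a separate spread (1604) and 0 at adjusted p under 0.01 (5984). Leaving out 1 library gave 1 to 5407: 5407 without pachytene control replicate 2, 20 without pachytene cKO replicate 1, 1, 1 and 8 without round spermatid control replicates 1, 2 and 3, and 18, 17 and 5 without round spermatid cKO replicates 1, 2 and 3. The round spermatid count of 38 moved to 21 with a pseudocount of 0.1, 68 with no minimum mean, 263 with only these libraries, 569 with a separate spread and 16 under 0.01. It ran from 12 to 74: 74 without pachytene control replicate 1 or 2, 12 and 17 without round spermatid control replicates 1 and 2, and 16, 16 and 18 without cKO replicates 1, 2 and 3. The count of 11 for the difference between stages moved to 6 with a pseudocount of 0.1, 31 with no minimum mean, 20 without the pseudogene pair, 1 with a separate spread, 19 under 0.10 and 7 under 0.01. It ran from 6 to 3257: 41 and 3257 without pachytene control replicates 1 and 2, 22 and 438 without pachytene cKO replicates 1 and 2, 7 without round spermatid control replicate 1 or 2, and 6 without round spermatid cKO replicate 1. The stage count of 12145 stayed between 8891 and 16128 in all settings run. The cause was not tested.

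With a replicate block the counts were 6583 in pachytene cells, 70 in round spermatids and 3241 for the difference, Ago2 in pachytene cells was −0.59 (adjusted p = 0.0208), and 5 lists were called in round spermatids, with round spermatid markers (adjusted p = 0.0323), flagellum genes (0.041) and macrophage markers (0.0243) added. In pachytene cells pachytene markers (0.0328) and ribosomal protein genes (0.00277) were added, and between stages sperm head genes (0.0166). The call of X-linked genes between stages (0.109) and that of round spermatid markers for the difference of effects (0.289) ended. Deviations of libraries with the same number correlated at r = 0.555 in pachytene cells, and at 0.179, 0.292 and 0.0229 in round spermatids, where control replicate 1 went best with cKO replicate 3 (0.274), so the numbers need not pair the samples.

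Ago2 in pachytene cells reached −0.61 (limma adjusted p = 0.0427) without the pseudogene pair and ran down to −0.82 without cKO replicate 2. Like every other gene, it did not pass with pachytene libraries alone or with a separate spread. The 9 pachytene lists called by camera became 0 with an estimated correlation (0 at unadjusted p under 0.05) and 4 with fry. These 4 were the splicing, piRNA, synapsis and AGO lists (fry adjusted p = 0.00607 to 0.016). The 2 round spermatid lists became 0 with an estimated correlation (0 at unadjusted p under 0.05), 0 with fry (1) and 4 with median-ratio scaling. They ran from 1 to 5: 5 without round spermatid control replicate 1 or cKO replicate 2, and 1 without control replicate 2. Y-linked genes in pachytene cells lost their call at −0.14 with an estimated correlation (adjusted p = 0.973) and fry (0.744), and at −0.0188 with median-ratio scaling (0.904). Their mean was −0.40 without pachytene control replicate 1 and 0.0187 without pachytene cKO replicate 1. In round spermatids it moved to −0.0421 with median-ratio scaling. The mean of X-linked genes in pachytene cells was −0.178 without cKO replicate 2 and −0.128 without cKO replicate 1. In round spermatids they lost their call at 0.11 with an estimated correlation (adjusted p = 0.973) and fry (0.376), and at 0.10 without control replicate 2 (0.09). The correlation of effects, 0.190, ran from 0.0853 without round spermatid cKO replicate 1 to 0.245 without cKO replicate 2, and was 0.131 without pachytene control replicate 2 or pachytene cKO replicate 1. The cause was not tested.

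Stricter peaks moved CDS, 3' UTR and intron shares to 13.4%, 8.50% and 45.6% in the first eCLIP list and 19.7%, 10.03% and 35.8% in the second. With 3' UTR before CDS, CDS and 3' UTR held 17.1% and 11.9%, and 25.1% and 14.1%. Without adapter matches the 3' UTR share was 9.48% in the first list, and CDS, 3' UTR and intron shares were 29.9%, 11.04% and 28.3% in the second. Peaks at the barcodes stay in this setting. Random placement within exons gave an overlap of 0.714% and 2.21%. The 1 seed called in the first list became 0 without extension, 0 with stricter peaks and 0 without adapter matches (Fisher's exact test, 1, 0 and 1 at unadjusted p under 0.05). Without extension that 1 was let-7 (ratio 2.19, Fisher's exact test, adjusted p = 0.207), and miR-202-5p had a ratio of 1.2. Without adapter matches it was miR-202-5p, with a ratio of 1.94 in place of 2.15. Target genes in pachytene cells lost their call at −0.30 with an estimated correlation (adjusted p = 0.737), at −0.27 with 3' UTR peaks only (0.103) and at −0.35 without pachytene control replicate 1 (0.299), in a range of −0.392 to −0.202 with 1 library left out. Of the named genes, 58 stayed on their side of the threshold and 12 lost their call with a pseudocount of 0.1, 53 and 17 with no minimum mean, and 37 and 25 with only the libraries compared. Of the single gene lists, 27 stayed on their side and 9 lost their call with an estimated correlation, and 31 and 5 with fry.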

Other observations

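The tests over all genes and over the piRNA list were planned, but the genes given here were picked only after their values were seen.

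Ddx4, a germ-cell RNA helicase of the piRNA pathway, was lower in the cKO libraries of both stages. In round spermatids it stood at 198, 249 and 242 TPM in control and 107, 130 and 114 TPM in cKO (229 ± 27.5 and 117 ± 12.05 TPM, SD, n = 3; log2 −0.96, SE 0.23), which did not pass over all genes tested (limma adjusted p = 0.277) and was the 1 gene lower adjusted over the piRNA list alone (0.045). In pachytene cells it stood at 74.3 and 119 TPM in control and 23.5 and 42.6 TPM in cKO. The difference between cKO and control in Ddx4 was not shown to differ between the stages (limma adjusted p = 0.353). The labels do not name the Cre driver, so whether this difference comes from the loss of Ago2 cannot be told from these data.

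Gm10800 and Gm10801, neighbouring genes on chromosome 2, were lower in pachytene cKO. Gm10800 stood at 1165 and 540 TPM in pachytene control and 50.8 and 89.2 TPM in pachytene cKO (log2 −3.54, limma adjusted p = 0.0169), with 8.23 to 14.7 TPM in round spermatids. Gm10801 stood at 56.0 ± 17.9 and 6.81 ± 3.74 TPM in the same pachytene groups (SD, n = 2, log2 −2.92, limma adjusted p = 0.0169). With pachytene libraries alone limma called 0 genes, so both calls carry little weight. Gm28438, an unprocessed pseudogene on chromosome 1, went from 143 to 1.43 TPM in round spermatid cKO (log2 −6.37, limma adjusted p = 0.00254), with 1.63 and 3.55 TPM in pachytene control and cKO. Whether the reads given to these genes come from other places in the genome was not tested.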
